A study of Homo sapiens with 6 samples.

How the data were processed

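RNA from HEK293T cells was analysed in 6 samples: 1 m6A-immunoprecipitated and 1 input library after TRMT10A knockdown, the same pair after control knockdown, and 2 CLIP replicates of TRMT10A. Groups and replicate numbers were taken from the sample titles. Knockdown was by transfected siRNA, per the labels' protocols, which also give poly(A) selection and depletion of ribosomal RNA without saying whether these applied to the CLIP libraries. The submitters' processing notes name the hg38 genome build, TopHat2 and Cuffdiff, with no role. The peak caller, the cluster caller and their thresholds are not given in the sources used here.

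The CLIP tables hold counts of conversion events per cluster and counts of clusters per line, as deposited by the authors and not normalized, per the file headers. In some CLIP protocols conversion events are base changes at crosslinked positions. Which protocol was used is not given in the sources used here. Every listed cluster had at least 2 events. A cluster listed under several genes was counted once in totals and once for every gene it was listed under. Multi-copy RNAs (rRNA, 7SL, small nuclear RNA, tRNA, histone genes) share sequence, so events at single copies are uncertain. The tables list clusters inside annotated transcripts only, so that RNAs outside them were not analysed here.

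The m6A table holds the authors' deposited log2 enrichment ratio of TRMT10A knockdown over control per peak, with a call of common or unique and the positions of GGACU motifs, per the file headers. How the ratio was normalized is not given in the sources used here. The table gives no values per library and no p-value. The gene columns and the ratio columns were found to be sorted separately, as tested by the share of motif positions inside the peak of their own line. Ratios were therefore described over the whole table, and tied to genes only through motif positions. For this, GGACT positions were found in the GENCODE release 29 transcripts that match the table's RefSeq accessions (97.3% of peaks). A ratio with several motifs was joined to a peak when exactly these positions, and no others, lay in that peak and in no other peak. The false share was estimated by shifting positions by up to 40 bases in steps of 4. In a test on simulated data, 300 simulated ratio cells were drawn from the motif patterns of the 26475 peaks themselves. All were joined to the right peak, which was fixed in advance because each pattern matched a single peak. The test thus checks the code only, and not differences between RefSeq and GENCODE transcripts. The 600 random cells gave 0 wrong joins. Symbols turned into dates by a spreadsheet (48 lines) were restored through gene identifiers.

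Clusters were assigned to classes of RNA from the file's gene and location columns, GENCODE small RNA genes on the same strand, and RefSeq tRNA genes of GRCh38.p14, for which strand was not used. MIR7641-2, which has 5S rRNA sequence, was counted with 5S rRNA. Clusters of the replicates were matched when they shared at least 1 base on the same strand. Shares carry 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. Values of the 2 CLIP replicates are given as mean and SD. Nothing in the labels says that the CLIP replicates came from separate cultures. With 1 library per knockdown arm no test of the conditions was possible, and no p-value is given. Gene lists were set against 10000 random lists. The planned matching on expression could not be made, because no expression values were in the tables. Lists of m6A-carrying genes were instead matched on transcript length in 20 bins (95.6% of 20056 protein-coding genes had a length). Random lists for CLIP targets were drawn unmatched from the genes of the m6A table, which takes the place of the planned Fisher's exact test. In a test on simulated data for the CLIP lists, 99.0% of lists with 9-fold enrichment among 9000 genes fell above the range, and 1.00% of unchanged lists fell outside it. The simulated lists were longer than most of the gene lists, so the test does not cover lists with few members.

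Several planned results could not be had from the table: changes of m6A-IP level and of input RNA level alone, the authors' calls by q-value, and the median change per gene list. Ratios per gene were planned, and ratios per peak were used. The 28 gene lists and the rule for named genes were fixed before the data were examined. The rule takes TRMT10A, the 10 highest and 10 lowest m6A changes, the 12 CLIP genes with the highest mean rank in both replicates, and the 8 highest and 4 lowest m6A changes among CLIP genes. It adds members of the m6A writer, eraser, reader and TRMT10 family lists that pass 2-fold or are in both CLIP replicates, and up to 4 members of other lists outside the central 95% of random lists. For m6A changes the rule was applied to the joined peaks, of which 1 that the rule names is not reported here. Other genes named in the text were chosen after their values were seen. Alternatives covered the fold limit, centring, cluster overlap, stricter CLIP lists, single replicates and backgrounds. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.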

Results

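The series profiled RNA targets of TRMT10A, a methyltransferase known for modifying guanosine 9 of tRNAs, in HEK293T cells, an established human embryonic kidney line. N6-methyladenosine (m6A) was mapped by immunoprecipitation of RNA with an m6A antibody. It was measured after siRNA knockdown of TRMT10A and after a control knockdown, with 1 immunoprecipitated and 1 input library in each arm. RNA bound by TRMT10A was mapped by crosslinking and immunoprecipitation (CLIP) in 2 replicates. The CLIP tables held 1675 clusters with 342690 conversion events in replicate 1 and 2183 clusters with 496030 events in replicate 2. The m6A table held 26475 peaks on 9282 transcripts of 9278 named genes, with 1 ratio of knockdown over control per line and no read counts. Sequencing depth behind the m6A ratios is therefore unknown, and they had no replicate check.

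The first question was which RNAs TRMT10A contacted. Ribosomal RNA and the RNA of the signal recognition particle carried most CLIP signal in both replicates. The 45S, 28S, 18S and 5.8S rRNAs held 66.1% ± 0.328 (SD, n = 2) of conversion events. The 5S rRNA and its copies held 13.6% ± 0.451, and 7SL RNA, the RNA core of the signal recognition particle, held 11.4% ± 0.119 with its copies (SD, n = 2 for both). Exons of messenger RNAs other than histone mRNAs held 0.525% ± 0.0705 of events (SD, n = 2), although they accounted for 436 of the clusters in replicate 1 and 802 in replicate 2. No control immunoprecipitation was analysed here, so the shares describe abundance in the CLIP libraries and not enrichment over cellular RNA.

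Among genes listed in both replicates, RNA28S5 ranked first with 129762 and 179951 events in replicates 1 and 2. RNA18S5 followed with 66928 and 107424 events, RNA45S5 with 60238 and 90201, LOC100507412 with 36218 and 52037, and RNA5-8S5 with 28040 and 39845. Clusters listed under several of these entries, such as those shared by LOC100507412 and RNA28S5, were counted for each. The counts therefore overlap, and the whole class held 225645 and 328914 events. The remaining places among the 12 highest genes went to the 5S genes RNA5S1 and RNA5S10 to RNA5S15, which shared the same 30 clusters and so carried identical values of 20590 and 28840 events. They were taken in alphabetical order from tied 5S genes, and RN7SL2 had more events in replicate 2 (29269). These near-identical copies cannot be told apart by their counts. Other structured RNAs were lower. The spliceosomal small nuclear RNAs and their copies held 1.64% ± 0.0582 of events, small nucleolar and Cajal body RNAs 0.870% ± 0.0628, 7SK RNA and copies 0.367% ± 0.0419, and the RNase P and MRP RNAs 0.357% ± 0.0234 (SD, n = 2 for each). Of the small nucleolar and Cajal body RNA genes, 114 were listed in both replicates. SNORD3A, which encodes the U3 RNA used in ribosomal RNA processing, had 490 and 627 events.

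**Figure D1:**
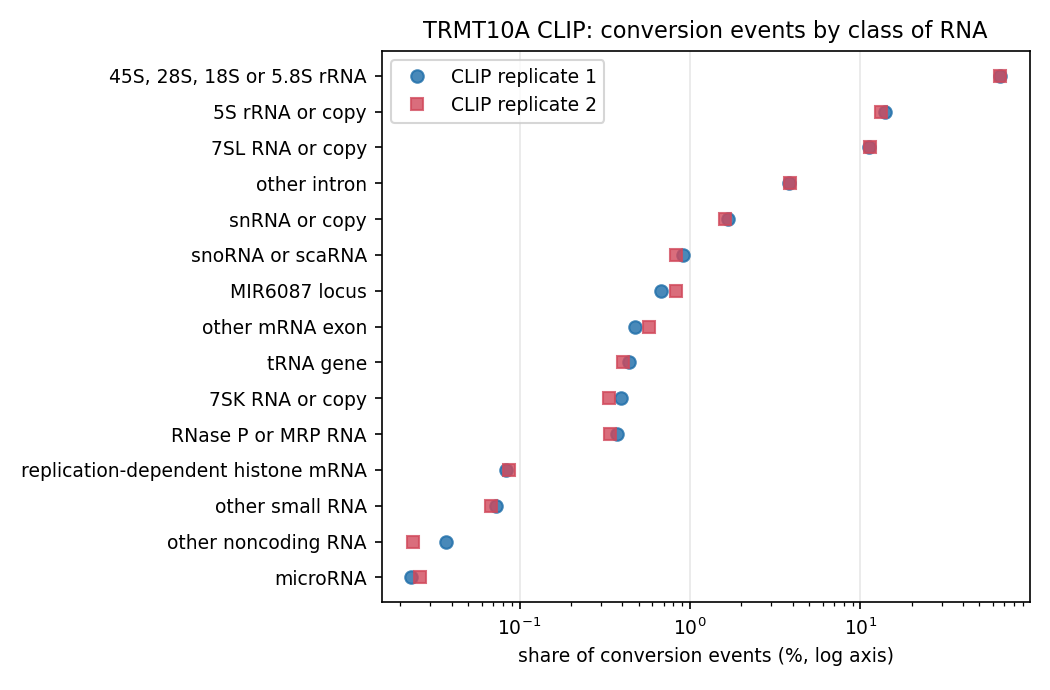
Share of conversion events by class of RNA in TRMT10A CLIP, in percent on a log axis; each point is 1 replicate. The 45S, 28S, 18S and 5.8S rRNAs lie at 65.8% and 66.3%, and exons of mRNAs other than histone mRNAs at 0.475% and 0.575%.

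The transcript of TRMT10A itself was among the mRNAs with the highest mean rank of conversion events. It had 6 clusters with 32 events in replicate 1 and 9 clusters with 76 events in replicate 2. Its largest cluster, with 21 and 50 events, lay at chromosome 4, 99549085 to 99549099 on the minus strand (hg38), which the file placed in the 3' UTR and which covers 99549091, 1 of 3 annotated ends of coding sequence among TRMT10A transcripts. All other TRMT10A clusters were placed in the coding sequence. Whether the CLIP cells carried an added TRMT10A construct is not given in the sources used here, and their siRNA label names TRMT10A without saying whether it was knocked down, so these events cannot be assigned to the endogenous transcript. The 15 mRNA genes with the highest mean rank, singled out after their values were seen because the fixed rule named only rRNA genes, were led by the histone gene HIST1H3B (84 and 158 events) and by RPL32 (102 and 112 events). The single RPL32 cluster lay in the 5' UTR at chromosome 3, 12840313 to 12840323 in replicate 1. Clusters placed in mRNA exons were classed as mRNA without a check for overlapping small RNA genes. A small RNA encoded within RPL32 is therefore not excluded as the source of its events. EEF2, the translation elongation factor that moves the ribosome along mRNA, had 73 and 88 events over 15 and 18 clusters. GNB2L1, now named RACK1 and encoding a protein of the small ribosomal subunit, had 39 and 91 events, and USP22 had 45 and 41. The glycolytic gene GAPDH had 41 events in each replicate.

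Clusters in mRNA exons lay mostly in coding sequence. In replicate 1, 69.4% of 481 clusters were coding (95% Wilson interval 65.2 to 73.4), 26.4% were in 3' UTRs and 4.16% in 5' UTRs. In replicate 2, the coding share was 68.4% of 855 clusters (95% interval 65.2 to 71.4), with 25.7% in 3' UTRs and 5.85% in 5' UTRs. The coding shares of the replicates thus lay within each other's intervals, which cover counting error only. Histone mRNAs were included. No random places were drawn for these shares, so they give the location of clusters and not a preference for coding sequence.

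Cytoplasmic ribosomal protein, replication-dependent histone and heat shock genes were listed in both replicates more often than random lists. Of 43 cytoplasmic ribosomal protein genes in the m6A table, which served as background, 15 were listed in both CLIP replicates, against a median of 1 in 10000 random lists (95% of lists 0 to 3). Over all ribosomal protein genes, inside or outside that background, 28 had exon clusters in both replicates, among them RPL32, RPL3 (35 and 32 events), RPL15 (31 and 42) and RPL30 (24 and 17). Of 16 genes of the histone list in the background, 9 were listed in both replicates, against a median of 0 (95% of lists 0 to 2). The list also took in H1F0 and H1FX, which are not replication-dependent and had clusters in replicate 2 only. HIST2H3A and HIST2H3C had identical counts, as did HIST2H4A and HIST2H4B, so the 9 are not all separate signals. HIST1H1C, a linker histone gene, had 47 and 63 events, and the identical genes HIST2H4A and HIST2H4B both had 34 and 36. Of 13 heat shock genes, 3 were listed, HSP90AB1 (8 and 2 events), HSP90AA1 (2 and 5) and HSPA8 (2 and 6), against a median of 0 (95% of lists 0 to 2). Against this background the other lists that could be compared did not exceed their random ranges, whereas against all protein-coding genes the m6A reader and common reference gene lists did as well. Lists with almost no members in the m6A table, such as the small nucleolar and Cajal body RNA genes, could not be compared. No mitochondrial ribosomal protein gene and no aminoacyl-tRNA synthetase gene of the lists was present in both replicates, which lay within their random ranges (0 to 4 and 0 to 2). With replicate 2 alone, 10 lists lay above their random range and 23 ribosomal protein genes were listed, and with replicate 1 alone 4 lists and 19 genes. Random lists could not be matched on expression, and highly expressed mRNAs give more CLIP reads.

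Of the m6A machinery, 3 genes were listed in both replicates. The demethylase gene ALKBH5 had 8 and 14 events, the reader gene PRRC2A 16 and 26, and the reader gene HNRNPA2B1 9 and 15. No m6A writer gene was listed in both, and TRMT10A was the only member of its family and of the tRNA methyltransferase list. Of the genes often cited for carrying m6A, MALAT1, a nuclear long noncoding RNA, had 6 and 4 events and SON had 5 and 17.

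The second question was how well the replicates matched. Of 680 genes in replicate 1 and 955 in replicate 2, 501 were listed in both, which is 73.7% and 52.5% of the lists. Restricted to genes of the m6A table, 331 and 532 genes shared 207, whereas random lists of these sizes shared a median of 19 (95% of lists 11 to 27). Across the 501 shared genes, log2 events correlated with Pearson's r = 0.972 and Spearman's rho = 0.880, with genes not being independent replicates. Gene copies with identical counts, such as the 5S genes, entered as separate points, and how far this raised r was not tested. Over the 176 mRNA genes with exon clusters in both replicates r was 0.827. Clusters sharing at least 1 base numbered 1196 in replicate 1 (71.4%) and 1228 in replicate 2 (56.3%). They held 98.4% and 97.8% of the events. Sharing followed depth. Of clusters with 2 events, 37.8% in replicate 1 and 16.2% in replicate 2 were found in the other replicate, compared with 94.6% and 95.3% of clusters with more than 20 events. Only 40.4% of mRNA exon clusters of replicate 1, histones excluded, recurred in replicate 2, and 23.3% in the opposite direction, so single mRNA sites were far less repeatable than rRNA sites (88.1% and 84.6%).

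**Figure D2:**
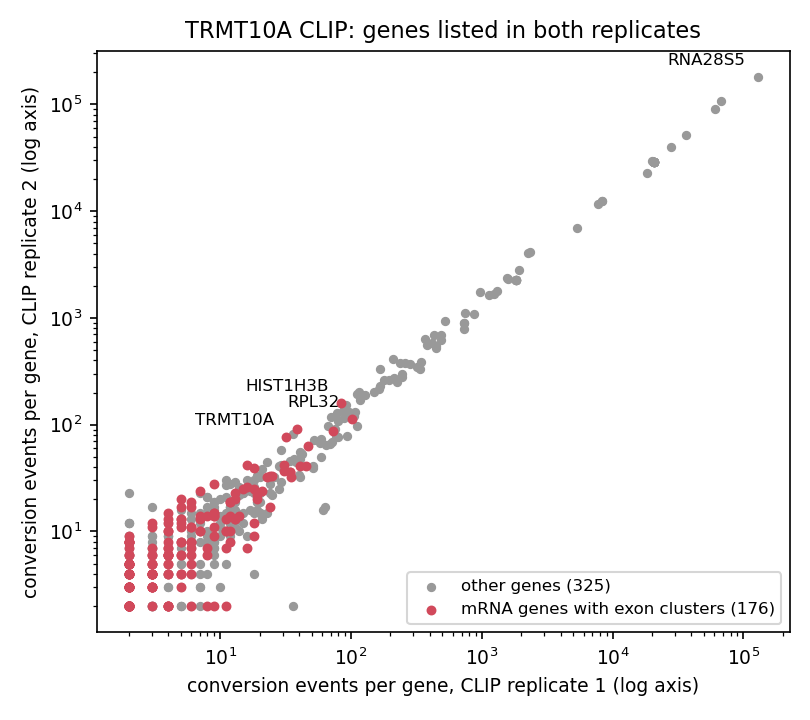
Conversion events per gene in replicate 1 against replicate 2 of TRMT10A CLIP, both on log axes, for the 501 genes listed in both; the 176 mRNA genes with exon clusters are in red. RNA28S5 stands at 129762 and 179951 events, and TRMT10A at 32 and 76.

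The third question was how m6A-IP enrichment differed after TRMT10A knockdown. TRMT10A had no line in the m6A table, so the knockdown could not be checked there. In the authors' deposited table, 4293 of 26475 peaks (16.2%, 95% Wilson interval 15.8 to 16.7) had a ratio at least 2-fold higher in the knockdown, and 1532 (5.79%, 5.51 to 6.07) at least 2-fold lower. The median log2 ratio of all peaks was 0.17. Higher ratios made up 73.7% of the peaks past 2-fold, and 56.9% (3189 higher and 2416 lower) once ratios were centred on that median. Most of the excess stood in peaks called unique, a term the file does not define. Whether that call rests on the ratio itself is not given in the sources used here. Of 6453 unique peaks, 2582 were at least 2-fold higher and 40 at least 2-fold lower, and 90.8% had a ratio above 0. Whether peaks called in the control arm alone could be listed is not given in the sources used here. The excess of higher ratios over all peaks therefore cannot be read as a gain of m6A. The 20022 common peaks had 1711 at least 2-fold higher and 1492 lower, with a median log2 ratio of -0.03.

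**Figure D3:**
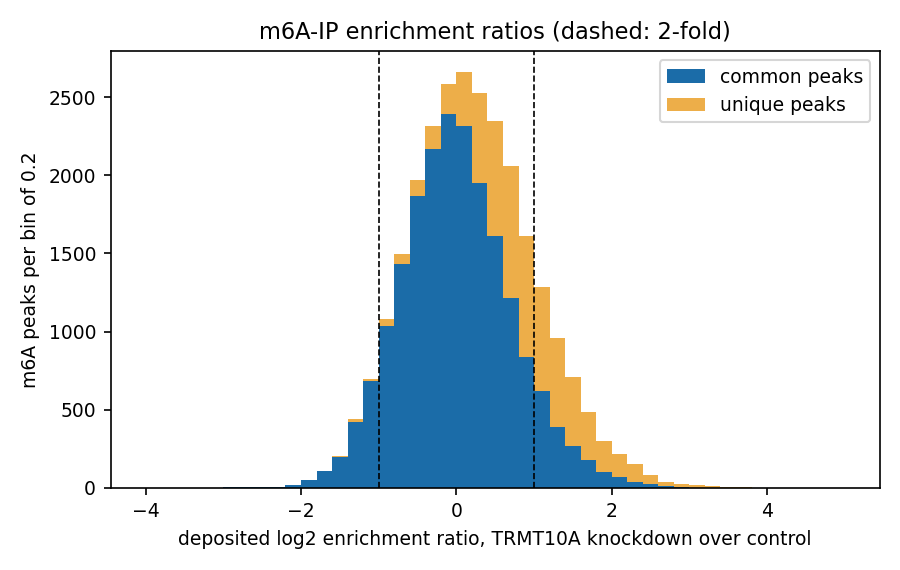
Deposited log2 enrichment ratios of the 26475 m6A peaks, TRMT10A knockdown over control, in bins of 0.2, stacked by the file's common and unique calls; dashed lines mark 2-fold. Unique peaks lie mostly above 0, and common peaks are centred near 0.

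Peaks that carried GGACU, the core sequence often methylated by the METTL3 complex, had lower ratios. Of the 1532 peaks at least 2-fold lower in the knockdown, 33.3% had a listed motif (95% Wilson interval 31.0 to 35.7). Of the 4293 peaks at least 2-fold higher, 17.6% had one (16.5 to 18.7). Among common peaks the shares were 33.5% and 19.7%. Peaks differed by the region of their first motif as well. The median log2 ratio was 0.23 for 533 peaks with the motif in the 5' UTR (95% bootstrap interval 0.14 to 0.31), 0.10 for 4079 in coding sequence (0.07 to 0.12) and -0.26 for 1572 in the 3' UTR (-0.29 to -0.21). Among common peaks the coding median changed sign to -0.04, and the 5' UTR and 3' UTR medians were 0.11 and -0.34. These intervals treat peaks as independent and cover the spread of peaks within 1 pair of arms.

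**Figure D4:**
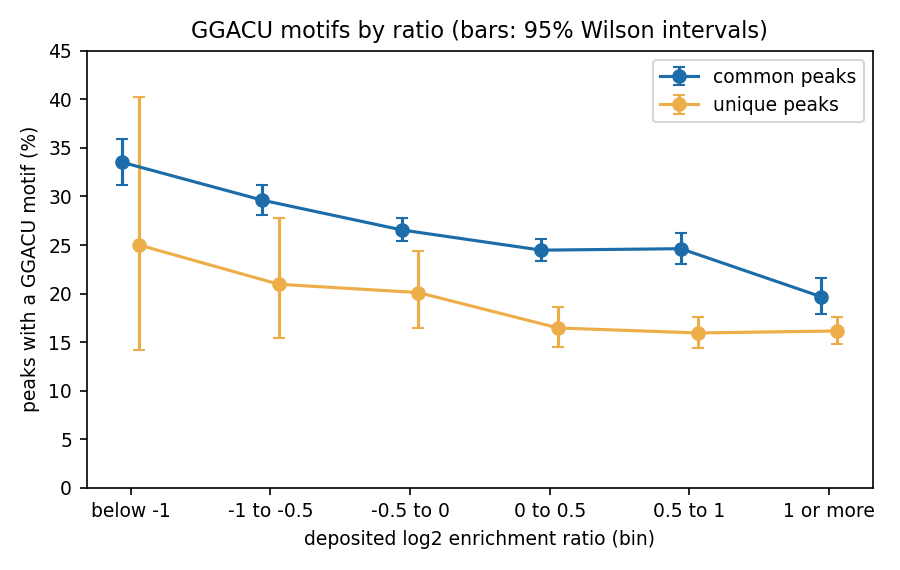
Share of m6A peaks with a GGACU motif, in percent, by bin of the deposited log2 enrichment ratio, for common and unique peaks; bars are 95% Wilson intervals. In common peaks the share goes from 33.5% in the lowest bin to 19.7% in the highest.

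Ratios could not be read off next to gene names. In the authors' deposited table the gene columns run by transcript accession and the ratio never rises from 1 line to the next. Listed motif positions fell inside the peak on their own line in 5.62% of cases, against 5.38% after shuffling (4.69 to 5.93 over 100 shuffles). Therefore 284 ratios, 1.07% of the table, were joined back to peaks of 269 genes through the exact positions of their GGACU motifs. Of these joins 282 also matched in transcript region, and positions shifted on purpose gave a mean of 3.95 joins, an expected false share of 1.39%. The joined peaks all held at least 2 motifs. Their median log2 ratio was -0.06, with 24 at least 2-fold higher and 33 at least 2-fold lower.

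Among the 284 joined peaks, peaks with some of the highest ratios in the authors' deposited table belonged to SYNE1, a nuclear envelope spectrin-repeat gene (log2 ratio 2.39), CDKAL1, a tRNA methylthiotransferase gene (2.27), and MPC1, a subunit of the mitochondrial pyruvate carrier (2.13). TNFAIP3, an inhibitor of NF-kappaB signalling, stood at 1.96, ABTB2 at 1.84, CDC23 of the anaphase-promoting complex at 1.58, and STIL, a centriole gene and a member of the primary microcephaly list, at 1.56. PCNX1 had 2 such peaks, at 1.86 and 1.53. The authors' deposited table called these peaks unique, except those of ABTB2 and STIL, which it called common. The CDKAL1 peak spanned transcript positions 11 to 160, with its first motif in the 5' UTR.

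The lowest ratios among the joined peaks in the authors' deposited table belonged to C19orf68, now named ZSWIM9 (log2 ratio -2.73), the palmitoyltransferase gene ZDHHC3 (-2.72), TMEM200B (-2.27) and CIAO1, a gene of cytosolic iron-sulfur assembly (-2.03). DDX52 stood at -1.80, TEX264 at -1.60, the histone chaperone gene SSRP1 at -1.52, CD99L2 at -1.50, PAFAH2 at -1.44 and the lysosomal cystine transporter gene CTNS at -1.40. All 10 were called common. For CIAO1 and DDX52 the listed region differed from the annotation, so that these 2 joins are the least certain.

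The fourth question was whether transcripts listed in the TRMT10A CLIP tables changed in m6A. Only 7 joined peaks belonged to genes listed in both CLIP replicates. In the authors' deposited table their log2 ratios were 0.28 for MCM7, a subunit of the replicative helicase, -0.00 for the clathrin heavy chain gene CLTC, -0.06 for HNRNPH1, -0.27 for SRRM2, -0.55 for PDE3A, -0.66 for ARF1 and -1.04 for LARP1, a regulator of ribosomal protein mRNA translation. The median was -0.27, compared with -0.06 for the other 277 joined peaks, and lay at percentile 26.9 of random lists of the same size. It was -0.17 for all genes of replicate 1. With single-motif joins added, a choice made after seeing the data, it was -0.07 over 15 peaks, against -0.04 for the other peaks there. The expected false share of those added joins was higher, at 15.7%. Of the 7 peaks 0 were at least 2-fold higher and 1, that of LARP1, at least 2-fold lower, against 24 and 32 of the 277 others. A difference was not detectable with 7 peaks. The PDE3A clusters lay in an intron, not in the exon that held its m6A peak. For the 6 peaks of genes with mRNA exon clusters in both replicates, also chosen after seeing the data, the median was -0.17 (percentile 37.0).

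Genes listed in both CLIP replicates often carried m6A peaks, although some were listed through intronic clusters only. Of 287 protein-coding genes listed in both CLIP replicates, 195 (67.9%, 95% Wilson interval 62.3 to 73.1) had at least 1 peak. Random lists matched on transcript length had a median of 137 (95% of lists 122 to 153). For the 173 genes with mRNA exon clusters in both replicates the share was 75.1%. LARP1, SRRM2, CLTC and ALKBH5 are examples with both an exon cluster and a peak, whereas GAPDH, RPL32 and TRMT10A had none of the peaks. Within transcripts, only clusters that could be placed on an annotated transcript of a gene with m6A peaks were compared, 348 of 481 mRNA exon clusters in replicate 1 and 647 of 855 in replicate 2. Of the 348, 23.3% overlapped an m6A peak, against a median of 20.1% for random places on the same transcripts (percentile 93.1). In replicate 2, 162 of the 647 did, against a median of 130 (percentile 99.9). Clusters that recurred in the other replicate gave 20.3% and 18.4% in replicates 1 and 2, within their random ranges (percentiles 65.9 and 45.7). Clusters and peaks both lay mostly in coding sequence, and this shared location was not separated from overlap as such. Expression could not be matched, and only expressed genes can give either signal.

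The m6A peaks were spread over many gene groups. KMT2D, a histone methyltransferase gene, had 22 peaks, followed by ZFHX3 with 20, RNF213 with 19, and HTT, HUWE1, PLEC and SYNE2 with 17 each. By position, 71.1% of 24732 peaks with an annotated coding sequence were centred in it, against 51.3% for random places on the same transcripts, and 19.6% in the 3' UTR, against 41.2%. Within 200 bases of the stop codon lay 17.9% of peak centres, against 11.3% at random. Of 28 gene lists, 19 had more members with peaks than length-matched random lists, 1 had fewer, 4 lay within the random range, and 4 were too small or held no protein-coding genes. All 13 m6A reader genes and 12 of 13 writer genes carried peaks, against medians of 8 and 7. METTL16 and CBLL1 had 6 peaks each, METTL3 had 2, and the demethylase genes ALKBH5 and FTO had 5 and 3. Of the mitochondrial ribosomal protein genes 60 of 78 carried peaks, against a median of 27. Genes of the ZNF zinc finger series were the list below its range, with 198 of 506 against a median of 267 (95% of lists 246 to 288). Of 8 markers each, 1 blood, 0 liver and pancreas and 2 fibroblast and muscle genes carried peaks. The random lists came from protein-coding genes matched on length and not on expression, and only expressed genes can give peaks. Common reference genes (12 of 14, against a median of 6) and proteasome genes (34 of 39, against 16) lay above their ranges too. These list results therefore cannot be told apart from expression.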

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

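All tests in this part were chosen after the results were seen. Events on tRNA genes appeared in the CLIP tables, although no line of these tables names a tRNA. There were 1498 events in replicate 1 and 2012 in replicate 2. They are given here because the planned list of tRNA genes, searched by gene symbol, could not reach them. Its 1 member in the m6A table was a protein-coding gene. With no control library analysed here, the events were set against no background. They touched 13 and 14 tRNA genes, 12 of them in both replicates. Of 465 annotated tRNA genes, 129 lie inside another gene, counted on either strand, so fewer may have been open to listing. The 2 histidine tRNA genes TRH-GTG1-7 and TRH-GTG1-8 in introns of SHF held 87.0% and 89.5% of these events. Their main clusters lay at chromosome 15, 45198626 to 45198655 and 45200433 to 45200462, on the minus strand (hg38). Other tRNA genes were far lower, such as TRG-GCC3-1 with 30 and 43 events and TRP-CGG1-3 with 26 and 30.

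The tables argue against binding along the SHF transcript, since 100% of the events listed under SHF lay on the tRNA genes in both replicates. Reads of 1 tRNA species counted at identical gene copies are a candidate explanation for the even split: TRH-GTG1-7 and TRH-GTG1-8 had 662 and 642 events in replicate 1 and 911 and 889 in replicate 2, with a largest difference of 0.554 standard errors of counting. Mature tRNA from any of the 9 annotated histidine tRNA genes could then appear there. No biological explanation was tested, since no control immunoprecipitation was analysed here.

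Lines without a gene symbol, which the comparisons by gene left out, held 2967 events in replicate 1 and 4867 in replicate 2. Of their 16 and 26 clusters, 15 and 24 also stood under a named gene.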

How the results depend on the processing

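No paired analysis was possible because each knockdown arm had 1 library and the CLIP replicates form 1 group. Alternatives on pseudocounts, low-value filters, q or p thresholds, the m6A-IP level alone, 4-fold CLIP enrichment and expression matching were not run, since the tables hold no values for them. Of 43 alternatives over 19 results, 16 stayed within the limits set for them, 26 moved and 1 reversed. Those on common peaks, mRNA exon clusters, shared clusters, joins and the protein-coding background, and all on the share of CLIP genes with m6A peaks, were chosen after seeing the data. Peaks higher in the knockdown numbered 8118 at 1.5-fold, 552 at 4-fold and 1711 among common peaks; peaks lower numbered 4238, 37 and, after centring, 2416. The share higher among peaks past 2-fold was 56.9% after centring and 53.4% among common peaks. The median ratio of peaks with a coding motif reversed to -0.041 among common peaks. Shared CLIP genes numbered 311 in the upper part of both lists, split at the median, 207 within the m6A table and 176 with mRNA exon clusters. Pearson's r was 0.999 untransformed, 0.987 in that upper part and 0.827 for mRNA genes. Gene lists above their random range numbered 4 to 10 with 1 replicate alone and 5 against all protein-coding genes. The share of CLIP genes with m6A peaks was 73.2% to 76.7% with 1 replicate alone and 75.1% for mRNA exon clusters. Clusters of replicate 2 inside m6A peaks were 18.4% when shared. The cause was not tested. The median m6A change of CLIP genes, -0.27, was -0.20 and -0.17 without replicates 1 and 2, -0.17 over 6 peaks for mRNA exon clusters, and -0.07 over 15 peaks with single-motif joins added, close to the -0.04 of the other peaks. Depth limits single mRNA sites, whose median was 2 events.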

Other observations

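All tests in this part were chosen after the results were seen, except that of the ratio along coding sequences.

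Several of the CLIP clusters with the most events stood in introns of protein-coding genes. EDA had 8289 and 12497 events in replicates 1 and 2 at chromosome X, 69672588 to 69672612, on the 5S rRNA pseudogene RNA5SP506. GREB1 had 7777 and 11636 events at chromosome 2, starting at 11584869, on the 7SL pseudogene RN7SL674P. SLC37A3, MED12L and PPP1R16B held similar copies. Of the clusters in introns of protein-coding genes, 44.1% in replicate 1 and 40.5% in replicate 2 lay on annotated small RNA genes, tRNA genes or their copies, against at most 1.96% in 1000 random placements in the introns of the same genes. These clusters held 67.6% and 67.8% of the intronic events. Reads of abundant RNAs placed on copies may thus account for most intronic signal. The rest stays open: SLCO5A1 (5374 and 6881 events) and PDE3A (2265 and 4064) had no such annotation at their clusters. Copies annotated only as repeats were not searched for, so copies at these clusters were not excluded. No biological explanation was tested.

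The lower ratios of peaks with GGACU, and of those with it in the 3' UTR, could come from unique peaks carrying fewer motifs. The tables argue against this as the whole cause, because common peaks alone had motifs in 33.5% at 2-fold down and 19.7% at 2-fold up. Noise in weak peaks, if it acted alike on both tails, would thin motifs in both. The 33.5% instead lay above the 25.6% of common peaks with log2 ratios between -0.5 and 0.5. Noise or a selection of peaks that acted on 1 tail more than the other was not tested, so the comparison cannot exclude it. A change of coverage along transcripts between libraries cannot be told apart. Across 198 joined peaks with a coding motif, the ratio and the position in the coding sequence had a Spearman's rho of -0.0957 (95% bootstrap interval -0.24 to 0.05), and the knockdown itself stays open and untested, with 1 library per arm.

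The joined peaks, a subset of the same ratios and so no separate evidence, had median log2 ratios of 0.23 for 30 peaks with their first motif in the 5' UTR, -0.03 for 199 in coding sequence and -0.39 for 54 in the 3' UTR.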
